A study of Mus musculus with 25 samples.

How the data were processed

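RNA from virus-specific CD8 T cells, sorted by flow cytometry from mouse spleens and placed in Trizol, had been labelled with biotin and hybridised to Affymetrix MG-U74v2 A, B and C arrays. A mouse age of 4 to 6 weeks was given for every group, whatever the day of infection. It is therefore not read as the age at sorting. The labels gave 15 A arrays (4 naive, 3 effector, 4 memory, 4 exhausted), 5 B arrays and 5 C arrays (1 naive, 1 effector, 1 memory and 2 exhausted each). Groups were taken from the labels alone. The labels speak of 3 biological replicates per group but number them 1 to 4 (effector 1 to 3), and the series design of 3 or 4 independent samples per cell type was followed. For 3 B arrays the description named the A array, and their titles were followed. The labels do not say that a replicate number marks a shared animal or day. Deviations from group means correlated over 0.1 in all 4 same-number pairs of naive and memory arrays (0.553, 0.414, 0.671 and 0.707) and in not every pair of any other comparison, so a block by number is given beside the memory and naive comparison and as an alternative elsewhere.

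The deposited values were probe set intensity on a linear scale, with no logarithm taken by the authors. The summary method, software and scaling were not given in the sources used here. Deposited medians differed by at most 6.39% between A arrays, 1.26% between B arrays and 2.14% between C arrays, so the arrays had been scaled before deposit. The lower and upper quartiles of the A arrays differed by 16.8% and 13.7%. By a rule fixed before the data were examined, arrays whose medians or quartiles differed by over 10% were quantile normalized, which applied to the A arrays. The B and C arrays, whose quartiles differed by at most 8.82% and 4.86%, were used as deposited. Values were then floored at the 20th percentile of each array type (35.79 on A, 19.43 on B and 11.67 on C, linear intensity), and log2 was taken. On the A arrays 1691 probe sets lay at the floor on all 15 arrays and stayed in the test. A fold against a group whose arrays all lay at the floor is given as a lower bound.

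Control probe sets were left out of the tests (66 on A, 66 on B, 0 on C), which left 12422, 12411 and 11868. The platform annotation gave 1 gene for 10833 A probe sets, several for 396 and none for 1193, and 8251 different genes in all. On B, 10581 probe sets had 1 gene and on C 7717, for 7542 and 5928 genes. No symbol needed updating, and no genome build was named for the probe sets, so no coordinates are given.

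On the A arrays, 1 linear model with a mean for each of 4 groups was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, two-sided), and 6 contrasts were tested. Residual degrees of freedom were 11 and the prior added 0.495. A probe set counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all 12422 probe sets. Errors of log2 changes are the standard errors of the model with the moderated variance, and errors of group means are SD. Probe sets that set exhausted cells apart passed in the same direction against each of the 3 other groups. The overlap of calls against naive cells was set beside independent draws, 100 simulations and fits with the naive arrays divided between the comparisons. The simulations drew unchanged groups and shared naive arrays with noise independent between probe sets.

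Before the data were examined, 25 gene lists were fixed, 17 of pathways or sample handling and 8 of other cell types. They were inhibitory receptors, NK-type receptors, cytotoxic granule genes, cytokines and chemokines, trafficking and adhesion, naive and memory maintenance, transcription factors of CD8 T cell differentiation, T cell receptor signalling, interferon-stimulated genes, cell cycle, ribosomal proteins, translation factors, oxidative phosphorylation, citric acid cycle, glycolysis, apoptosis and TNF receptor genes, and immediate early and heat shock genes. The markers were those of B cells, plasma cells, macrophages with monocytes and dendritic cells, neutrophils, erythroid cells, platelets, NK cells and CD4 T cells. Each gene was represented by the probe set with the highest mean. Lists were tested with camera (preset correlation 0.01, two-sided, adjusted over all 150 tests of lists and contrasts), and again with an estimated correlation and with fry. Of the 150 tests 60 passed with the preset correlation, 15 with an estimated correlation and 41 with fry. Fry tests whether the genes of a list move on balance one way and does not compare the list with other genes.

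Named genes followed a rule fixed before the data were examined. Per contrast these were the 8 genes with the largest increase and the 8 with the largest decrease among probe sets that passed, had a single gene and had every array of one group above every array of the other, then up to 4 members of each list described, and 19 marker genes. For the genes that set exhausted cells apart, the 12 with the largest smallest change were named in each direction, and for the B and C arrays the 5 with the largest smallest gap. Calls by only some of a gene's probe sets are stated. On the B and C arrays the single naive, effector and memory arrays had no spread of their own, so limma took the spread of the 2 exhausted arrays for all groups (1 residual degree of freedom), and the main measure was a 2-fold gap of both exhausted arrays to each other array, without a test. Tables of different array types were not combined.

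RNA quality was read from the control probe sets of beta-actin and Gapdh, as the log2 signal of the 3' probe set minus that of the 5' probe set, and from the interquartile range of the deposited values. The 4 exhausted arrays were compared with the other 11 by an exact permutation test over all 1365 splits, adjusted over the 3 measures, a test run because a difference was seen.

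Alternatives planned before the data were examined were values as deposited, median centring, floors at the 10th and 40th percentiles, a filter on dim probe sets, a variance trend with robust moderation, no moderation, a fit of only the 2 groups compared, a block by replicate number, array weights, a minimum change of 2-fold, removal of each array, and for the lists an estimated correlation, fry and the mean of all probe sets of a gene. Array weights were estimated gene by gene because the default estimation did not converge. Chosen after seeing the data were removal of probe sets at the floor on all arrays, removal of exhausted array 3 with effector array 2, a block by number in a fit of only the naive and memory arrays, and covariates for the beta-actin difference and for the first component of within-group deviations. The number of arrays, and not a count of molecules, limits the precision. The pipeline was tested on simulated data with 200 of 12422 probe sets changed between exhausted and memory arrays in 20 simulations: it recovered 27.9% of 1.5-fold, 56% of 2-fold, 92.5% of 4-fold and 98.4% of 8-fold changes, with 5.6% of calls false. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.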

Results

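Gene expression was measured in virus-specific CD8 T cells sorted from mouse spleen, before and during infection with lymphocytic choriomeningitis virus (LCMV). The series compared 4 groups: naive cells from uninfected mice (day 0), effector cells at day 8 of acute infection, memory cells from day 30 after acute infection, and exhausted cells from day 22 to 35 of chronic infection. The 25 arrays came from the 3 Affymetrix designs of the MG-U74v2 set. The A array had replicates, with 4 naive, 3 effector, 4 memory and 4 exhausted arrays. The B and C arrays each had 1 naive, 1 effector, 1 memory and 2 exhausted arrays. Exhausted replicate 1 held cells specific for the GP276 epitope, and all other arrays held cells specific for GP33. On the A arrays the deposited median intensity ranged from 105.7 to 112.4, and the number of arrays per group limited the precision of every comparison.

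T cell transcripts were high in all groups, and the exhausted arrays differed from the rest in signs of RNA quality. Cd8a, a coreceptor chain of CD8 T cells, had a mean log2 intensity of 11.56 ± 0.06 (SD, n = 4) in naive, 11.08 ± 0.53 (n = 3) in effector, 11.23 ± 0.08 (n = 4) in memory and 10.87 ± 0.44 (n = 4) in exhausted cells. The beta-actin control signal from the 3' end exceeded that from the 5' end by a log2 difference of 1.64 ± 0.97 (SD, n = 4) on the exhausted arrays and 0.54 ± 0.23 (n = 11) on the others (exact two-sided permutation test, p = 0.0044; 0.0132 adjusted over the 3 quality measures). The values of exhausted arrays 1 to 4 were 1.93, 0.51, 2.80 and 1.30, so array 2 lay within the range of the other groups, 0.12 to 0.89. For Gapdh the difference was 2.95 on exhausted and 1.95 on other arrays (exact permutation p = 0.044, adjusted 0.0527). The interquartile range of the deposited log2 values was 2.38 against 2.51 (exact permutation p = 0.0527, adjusted 0.0527). Exhausted array 3 had the widest beta-actin difference, and its rank correlations with the other 14 arrays, across genes, were 0.849 to 0.925. Effector array 2 had the smallest beta-actin difference, 0.12, and the smallest Gapdh difference, 0.28.

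**Figure D1:**
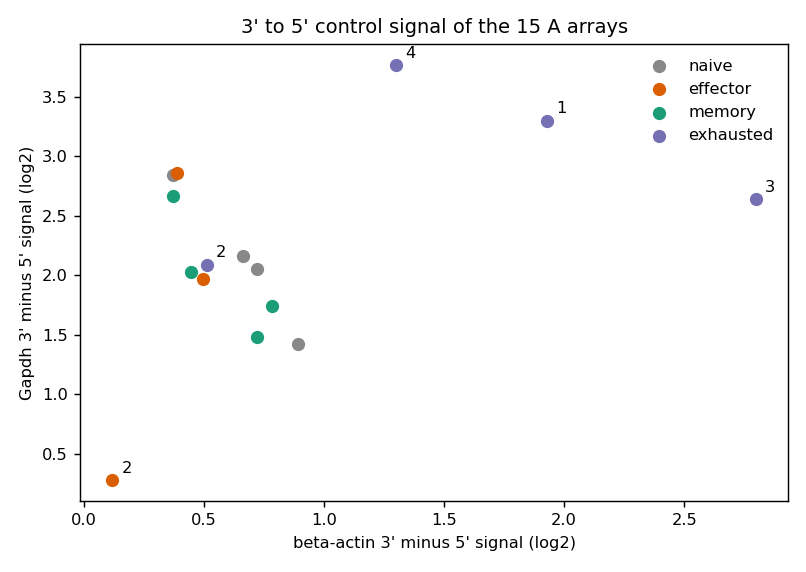
Control probe set signals on the 15 A arrays, with the 3' minus 5' log2 difference of beta-actin on the horizontal axis and of Gapdh on the vertical axis. Each point is 1 array coloured by group, with replicate numbers for the exhausted arrays and effector array 2; exhausted arrays 1, 3 and 4 lie at 1.93, 2.80 and 1.30 for beta-actin, above all others.

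Marker genes fixed before the data were examined separated the groups by differentiation state. Pdcd1, which encodes the inhibitory receptor PD-1, averaged a log2 intensity of 8.77 ± 1.28 (SD, n = 4) in exhausted cells, against 6.36 ± 0.13 in memory, 6.67 ± 0.15 (n = 3) in effector and 6.35 ± 0.29 in naive cells. Il7r, the receptor for the survival cytokine interleukin 7, averaged 11.67 ± 0.23 in memory, 10.90 ± 0.39 in naive, 9.26 ± 0.60 in exhausted and 8.56 ± 0.29 in effector cells. Granzyme B (Gzmb), a cytotoxic protease, averaged 11.71 ± 0.43 in effector, 10.94 ± 0.61 in exhausted, 9.37 ± 0.25 in memory and 7.04 ± 0.20 in naive cells. Klrg1, a receptor of terminally differentiated effector cells, averaged 10.70 ± 0.87 in effector, 8.55 ± 0.52 in memory, 6.94 ± 0.90 in exhausted and 5.72 ± 0.23 in naive cells. The lymph node homing receptor Ccr7 averaged 8.49 ± 0.38 in naive, 7.31 ± 0.30 in memory, 5.96 ± 0.36 in exhausted and 5.52 ± 0.36 in effector cells. Of the 19 marker genes, 16 had a probe set on the A array assigned to them alone.

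**Figure D2:**
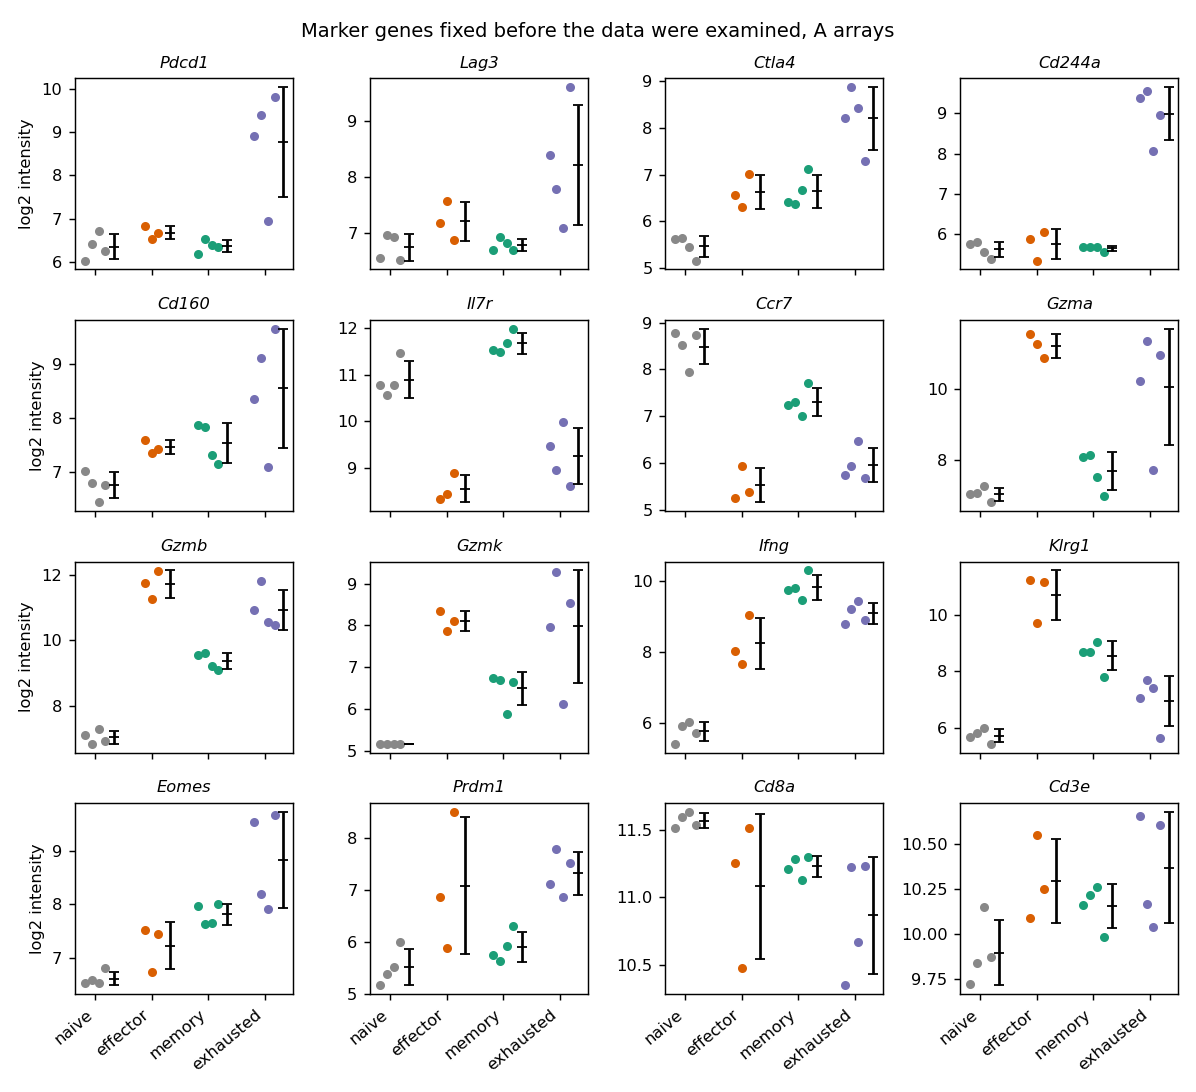
Log2 intensity of 16 marker genes on the A arrays, by group. Points are arrays and bars are the mean ± SD (n = 4, or 3 for effector), and each panel has its own axis; Cd244a lies at 8.99 ± 0.66 in exhausted cells and at 5.61 to 5.75 on average in the other groups.

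The comparison of exhausted with memory cells asked how antigen-experienced cells differ between persistent and cleared infection. Inhibitory receptors were higher in exhausted cells: Cd244a, which encodes 2B4, was 10.2-fold higher (log2 change 3.35 ± 0.27 SE, adjusted p = 1.49e-04) and Pdcd1 was 5.31-fold higher (2.41 ± 0.48, adjusted p = 0.0267). The chemokine gene Ccl3 was 6.73-fold higher, and Rgs16, a regulator of G protein signalling, was 6.33-fold higher. Il7r was 5.34-fold lower (log2 change -2.42 ± 0.29, adjusted p = 0.0018), and Satb1, a chromatin organizer of T cells, was 4.93-fold lower (-2.30 ± 0.26). All 4 exhausted arrays lay on the same side of all 4 memory arrays for each of these genes.

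Among the other large increases over memory cells, Gpd2, a mitochondrial glycerol phosphate dehydrogenase, was 4.44-fold higher, the phospholipid scramblase gene Plscr1 4.13-fold higher and the endosomal tether gene Eea1 4.03-fold higher. Pbx3, at the floor on all memory arrays, was at least 6.31-fold higher by 1 of its 3 probe sets. The large decreases included Dgka, a diacylglycerol kinase that limits T cell receptor signals (5.75-fold), the activator protein genes Fosb (5.23-fold) and Fos (4.71-fold, 1 of 2 probe sets), the potassium channel gene Kcnj8 (4.65-fold), the gut homing integrin chain Itgb7 (4.13-fold, 1 of 2 probe sets) and the actin regulator Evl (4.01-fold, 1 of 2 probe sets). Granzyme B was 2.96-fold higher and Fasl, a death ligand, 3.05-fold higher, whereas the lysosomal membrane gene Lamp1 was 1.95-fold lower. Several markers did not pass the test: the log2 changes were 1.43 ± 0.41 for Lag3 (adjusted p = 0.135), 1.01 ± 0.43 for Cd160 (0.33), 2.36 ± 0.63 for Gzma (0.104), 1.49 ± 0.51 for Gzmk (0.207), -0.74 ± 0.29 for Ifng (0.276), -1.61 ± 0.46 for Klrg1 (0.135), 1.01 ± 0.36 for Eomes (0.221) and 1.42 ± 0.45 for Prdm1 (0.167).

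In this comparison 218 of 12422 probe sets passed the limma test, 80 higher and 138 lower in exhausted cells, which stood for 64 and 123 genes. A change of at least 2-fold was seen in 39 of those higher and 62 of those lower. With beta-actin 3' to 5' signal as a covariate, an alternative chosen after seeing the data, the split between directions turned to 107 higher and 52 lower, and 86 of the 218 were kept. It was 189 higher and 178 lower without exhausted array 3. The covariate had an SD of 0.97 among the 4 exhausted arrays and 0.23 among the other 11. It therefore rested largely on exhausted arrays 2 (0.51) and 3 (2.80) and could not separate RNA quality from other traits of these arrays. This holds for every comparison. The count was 711 without exhausted array 2, 367 without exhausted array 3, 131 without exhausted array 1, and 93, 94 and 111 without memory arrays 1, 2 and 4. Of the 56 calls of named genes in this comparison, 30, among them Cd244a, Rgs16, Il7r and Satb1, held in all 15 fits that left out 1 array. With the beta-actin covariate 20, among them Ctla4, Ccr7 and Fos, did not pass. The Pdcd1 call was lost without memory array 1, 2, 3 or 4 or exhausted array 1 or 4 (adjusted p = 0.0613 to 0.0848). That of Ccl3 was lost without memory array 2 or 4 (0.052 and 0.0522) and that of Gzmb without memory array 4 (0.0527). Exhausted array 3 held down some folds, which without it were 10.3 for Ccl3, at least 10.1 for Pbx3 and 8.11 for Pdcd1. Some calls were lost more often: Plscr1 and Pgam1 in 12 of the 15 fits, Bcl2l11, Dnajb1 and Cd22 in 11, Nfatc1 in 9, Pbx3 in 8, Fos and Il10 in 7 and Ctla4 in 4.

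Genes of naive and memory maintenance and immediate early genes each fell as a list in exhausted against memory cells. The immediate early and heat shock list was fixed as a sign of sample handling, and it was higher in memory cells than in each other group. A handling difference of the memory samples was not tested. Of 13 measured maintenance genes 4 fell and none rose, with 5 lower when adjusted over the list alone (camera adjusted p = 5.08e-04, or 0.031 with an estimated correlation). They were Il7r, Satb1, Ccr7 (2.56-fold lower) and Klf2, a factor that maintains quiescence and egress receptors (2.42-fold lower). Of 18 immediate early and heat shock genes 5 fell and none rose, and adjusted over the list alone 11 were lower and 1 higher (adjusted p = 3.72e-08, or 0.0356 with an estimated correlation). Besides Fosb and Fos, these included the mRNA decay factor Zfp36 (2.66-fold lower) and the heat shock gene Dnajb1 (1.69-fold lower). Both lists lost their call with an estimated correlation when exhausted array 3 was left out (adjusted p = 0.0656 for each).

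Of 16 inhibitory receptors 4 rose in exhausted over memory cells and none fell, and adjusted over the list alone 7 were higher and 2 lower (adjusted p = 1.74e-04, or 0.118 with an estimated correlation). Beside Cd244a and Pdcd1 these were Ctla4 (2.95-fold) and Entpd1, the ectoenzyme CD39 (2.88-fold). Because receptors on this list are known from study of these very samples, its direction was not independent evidence. Whether members of the other lists and the marker genes were known in the same way was not assessed. In the fit lacking exhausted array 3, 8 rose and the list passed also with an estimated correlation (adjusted p = 0.00872). The 49 cell cycle genes shifted upward as a list (median log2 change 0.39, 44 of 49 positive, adjusted p = 6.31e-09, or 0.282 with an estimated correlation), although none passed singly and 3 were higher when adjusted over the list alone. Of 20 cytokines and chemokines, Ccl3 and Il10 (1.31-fold) rose, also when adjusted over the list alone (adjusted p = 0.0433, or 0.281 with an estimated correlation; 0.0745 without effector array 2). Of 30 interferon-stimulated genes only Rsad2, an antiviral enzyme, rose (2.80-fold), and 4 were higher when adjusted over the list alone (adjusted p = 0.0408, or 0.769 with an estimated correlation). When exhausted array 3 was left out, 8 rose (adjusted p = 3.64e-08, or 0.117 with an estimated correlation), and with the beta-actin covariate the adjusted p was 6.48e-20.

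Lists of T cell receptor signalling and metabolism shifted downward in exhausted against memory cells, and none of these shifts passed with an estimated correlation. For T cell receptor signalling 2 of 24 genes fell, Dgka and the phosphatase gene Ptpn6 (2.64-fold lower), both negative regulators of the signal, and the same number was lower when adjusted over the list alone (adjusted p = 0.00268, or 0.262 with an estimated correlation). None of 40 translation factors passed singly and 5 were lower when adjusted over the list alone (adjusted p = 0.00112, or 0.19 with an estimated correlation). None of 35 ribosomal protein genes passed by either adjustment (adjusted p = 0.0386, or 0.465 with an estimated correlation), nor did any of 21 citric acid cycle genes (adjusted p = 7.53e-04, or 0.395 with an estimated correlation). Of 15 glycolysis genes Pgam1 fell (1.64-fold), and 5 were lower when adjusted over the list alone (adjusted p = 0.0122, or 0.159 with an estimated correlation). These shifts were not stable when the fit included the beta-actin 3' to 5' difference, which varied mainly among the exhausted arrays. With it as a covariate the shifts of T cell receptor signalling (adjusted p = 0.844) and the citric acid cycle (0.85) turned upward without passing. Those of ribosomal proteins (0.688), translation factors (0.791) and glycolysis (0.142) no longer passed. Without exhausted array 3 the adjusted p was 0.258 for T cell receptor signalling, 0.147 for ribosomal proteins (0.0589 without effector array 2), 0.0755 for translation factors and 0.0524 for the citric acid cycle.

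Other lists did not pass as a whole between exhausted and memory cells, but some did in other fits. Transcription factors, apoptosis genes and oxidative phosphorylation passed upward with the beta-actin covariate (adjusted p = 0.00391, 2.28e-04 and 0.0372) and without exhausted array 3 (0.0086, 0.0215 and 0.0106, or 0.107, 0.192 and 0.346 with an estimated correlation). Of 30 transcription factors of CD8 T cell differentiation 4 rose and 2 fell, and 11 were higher and 3 lower when adjusted over the list alone (adjusted p = 0.0535). Nfatc1 (2.97-fold), the orphan receptor gene Nr4a2 (2.88-fold, 1 of 2 probe sets) and the hypoxia factor Hif1a (2.68-fold) rose, and Klf4 fell (2.45-fold, 1 of 2 probe sets). Of 20 trafficking genes 3 rose and 4 fell (3 and 6 adjusted over the list alone; adjusted p = 0.139), among them the tetraspanin gene Cd9 (3.23-fold higher), the integrin gene Itgav (2.82-fold higher, 1 of 3 probe sets) and the chemokine receptor gene Ccr2 (3.92-fold lower). Of 15 cytotoxic genes 2 rose and 1 fell (4 and 3 adjusted over the list alone; adjusted p = 0.602). Of 20 apoptosis and TNF receptor genes 3 rose, Fasl, Tnfrsf4 (1.70-fold) and Bcl2l11 (1.69-fold, 1 of 3 probe sets), and none fell (3 higher adjusted over the list alone; adjusted p = 0.171). Of 6 NK-type receptors, whose related probe sets may cross-hybridise, Klrd1 (2.60-fold) and Klrk1 (2.35-fold) fell (2 lower adjusted over the list alone; adjusted p = 0.274). None of 68 oxidative phosphorylation genes passed by either adjustment (adjusted p = 0.943).

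Markers of other cell types were measured beside these groups. Among 6 CD4 T cell markers Tnfrsf4, also an activation receptor of CD8 T cells, rose, and 2 were higher when adjusted over the list alone (adjusted p = 0.0114, or 0.243 with an estimated correlation; 0.0602 without exhausted array 3 and 0.307 with the beta-actin covariate). B cell markers did not shift as a list (adjusted p = 0.0548), although Cd22 was 1.99-fold higher in exhausted cells. Nor did plasma cell (0.989), macrophage, monocyte and dendritic cell (0.257), neutrophil (0.114), erythroid (0.78), platelet (0.437) or NK cell markers (0.83). Itgax, an integrin chain of dendritic cells that activated CD8 T cells also express, fell 2.38-fold.

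**Figure D3:**
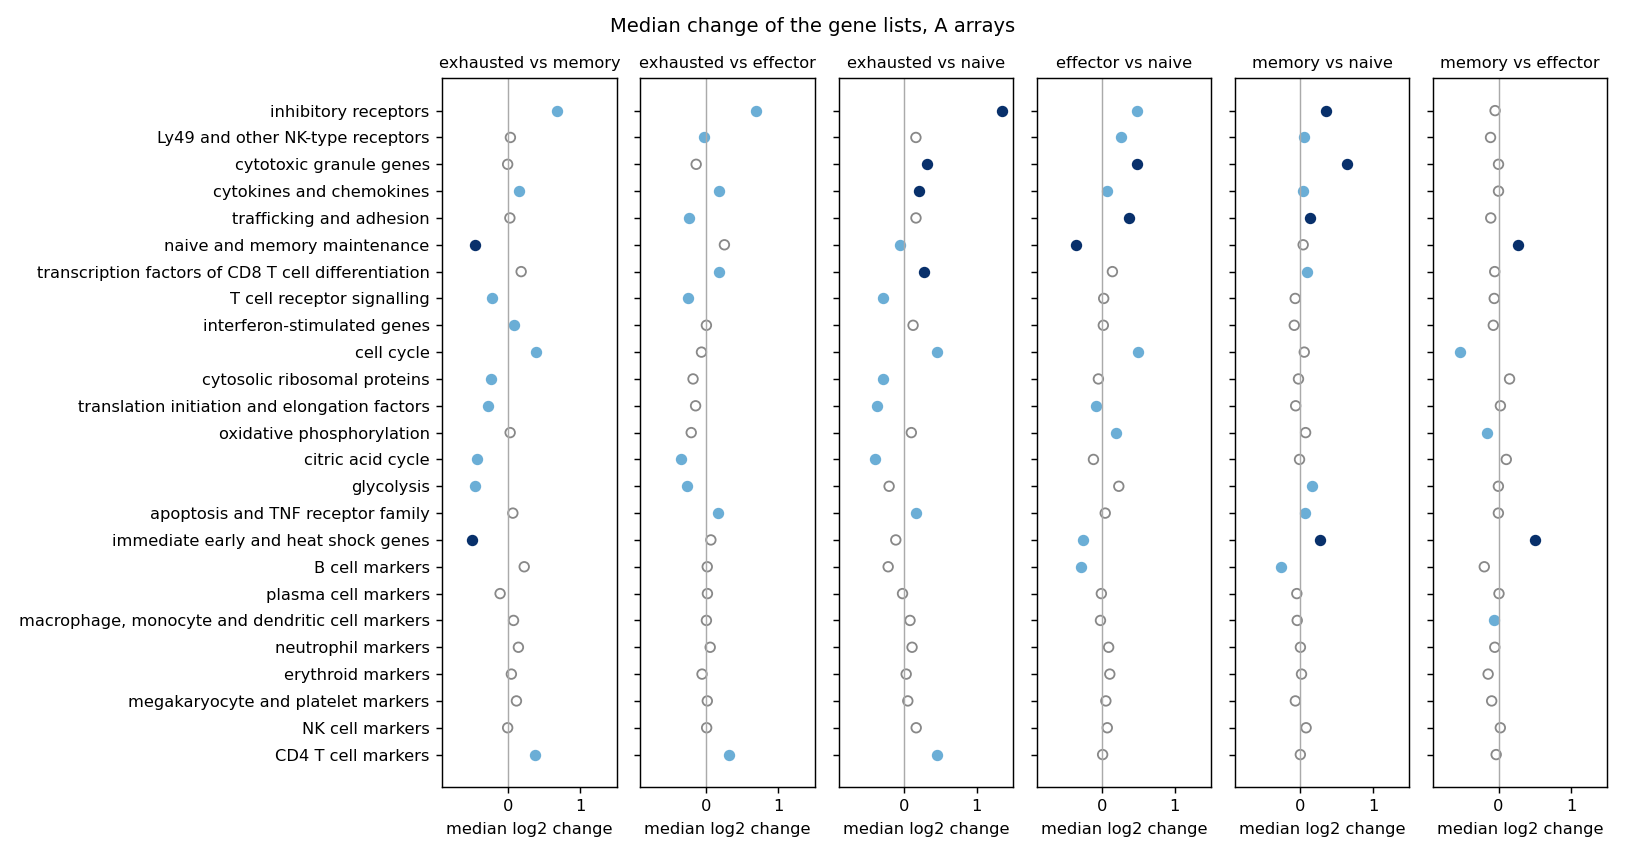
Median log2 change of 25 gene lists in the 6 comparisons of the A arrays, first group over second. Open grey points did not pass camera, light blue points passed with the preset correlation alone and dark blue points also with an estimated correlation; 60 of 150 tests passed in the first sense and 15 in the second.

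The comparison of exhausted with effector cells set late chronic against early acute infection. Klrg1 was 13.6-fold lower in exhausted cells (log2 change -3.76 ± 0.50 SE, adjusted p = 0.0049), the chemokine receptor gene Ccr2 11.1-fold lower (-3.47 ± 0.27), the annexin gene Anxa1 7.82-fold lower (2 of 3 probe sets) and Itgax 5.81-fold lower. Cd244a was 9.47-fold higher (3.24 ± 0.30, adjusted p = 2.68e-04) and Rgs16 5.76-fold higher (1 of 2 probe sets). Eomes, a T-box factor of effector and memory cells, was 4.79-fold higher by 1 of 2 probe sets, and the survival gene Bcl2 4.59-fold higher by 1 of 3. Further increases were seen in Lclat1, a cardiolipin acyltransferase (3.94-fold), the phosphatase gene Dusp6 (3.88-fold, 1 of 2 probe sets), Nr4a2 (3.70-fold, 1 of 2 probe sets) and the costimulatory receptor gene Tnfrsf9, at the floor in effector cells (at least 3.50-fold, 1 of 2 probe sets). Further decreases were seen in Plac8 (5.22-fold), the interleukin 18 receptor chain Il18rap (5.21-fold), the sphingosine phosphate receptor gene S1pr4 (3.80-fold) and the NK receptor gene Klrc1 (3.75-fold).

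Changes in granzymes and in most inhibitory receptors did not pass the test between exhausted and effector cells. The log2 changes were 2.10 ± 0.52 for Pdcd1 (adjusted p = 0.096), 1.57 ± 0.33 for Ctla4 (0.0524), -0.77 ± 0.30 for Gzmb (0.319), -1.15 ± 0.68 for Gzma (0.572) and 0.70 ± 0.31 for Il7r (0.402). The Pdcd1 result rested on exhausted array 3, with a log2 intensity of 6.93 there and at least 8.91 on the other exhausted arrays. Without array 3, Pdcd1 and Cd160 passed limma against each other group (largest adjusted p = 1.70e-04 and 0.0259), whereas Ctla4 and Lag3 did not pass against all of them. Of 16 inhibitory receptors Cd244a rose and Klrg1 and Klrc1 fell, and 6 were higher and 2 lower when adjusted over the list alone, which was not independent evidence for the reason given above (adjusted p = 0.00112, or 0.158 with an estimated correlation and 0.0125 when exhausted array 3 was also left out). Of 20 trafficking genes 2 rose, Itgav (2.61-fold, 1 of 3 probe sets) and the chemokine-binding receptor gene Ccrl2 (2.33-fold), and 3 fell, among them Ccr2 and Itgb7 (3.51-fold, 1 of 2 probe sets), with 2 higher and 5 lower when adjusted over the list alone (adjusted p = 0.0393, or 0.142 with an estimated correlation). Of 30 transcription factors Nr4a2 and Egr2 (2.28-fold), both induced by T cell receptor signals, rose and none fell, and 7 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.0106, or 0.142 with an estimated correlation). Of 6 NK-type receptors Klrd1 (3.19-fold) and Klrk1 (2.42-fold) fell (2 lower adjusted over the list alone; adjusted p = 0.0355, or 0.279 with an estimated correlation). Fasl (2.98-fold) was the only riser of 20 apoptosis and TNF receptor genes, with 3 higher when adjusted over the list alone (adjusted p = 0.0392, or 0.251 with an estimated correlation).

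Other lists that passed in this comparison shifted with at most 1 member past the test singly. T cell receptor signalling shifted downward, with Ptpn6 the only gene of 24 to fall (3.01-fold; 3 lower adjusted over the list alone; adjusted p = 7.39e-04, or 0.19 with an estimated correlation). The 21 citric acid cycle genes (adjusted p = 0.00847, or 0.498 with an estimated correlation) and 15 glycolysis genes (0.00861, or 0.142 with an estimated correlation) shifted downward with none and 1 lower when adjusted over the list alone. With the beta-actin difference as a covariate, T cell receptor signalling (adjusted p = 0.683) and the citric acid cycle (0.186) turned upward without passing, and glycolysis (0.334), trafficking (0.755), NK-type receptors (0.496) and CD4 T cell markers (0.623) no longer passed. The 20 cytokines and chemokines shifted upward with none past the test singly, and 2 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.0111, or 0.186 with an estimated correlation). Among 6 CD4 T cell markers none passed singly and 2 were higher when adjusted over the list alone (adjusted p = 0.0207, or 0.267 with an estimated correlation). Maintenance genes did not shift as a list (adjusted p = 0.514), although Satb1 fell 2.96-fold. Without exhausted array 3 the calls of NK-type receptors (adjusted p = 0.104), trafficking (0.218), T cell receptor signalling (0.0873), the citric acid cycle (0.219) and CD4 T cell markers (0.11) ended, and without effector array 2 those of trafficking (0.058) and apoptosis genes (0.116). Interferon-stimulated genes, which did not pass on all arrays (adjusted p = 0.304), passed upward without exhausted array 3 (9.09e-06, or 0.194 with an estimated correlation) and with the beta-actin covariate (9.16e-17). Without effector array 2, cell cycle genes (2.27e-04) and translation factors (0.019) passed downward and neutrophil markers (0.0113) passed upward.

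The test called 106 probe sets between exhausted and effector cells, 38 higher and 68 lower, for 29 and 60 genes. Of the 35 splits of these 7 arrays into groups of the same sizes, 5 gave as many, so chance was not excluded for this count, which was 5 when only the arrays of both groups were fitted. It was 539 without exhausted array 2, 285 without exhausted array 3, 45 without effector array 1 and 67 without exhausted array 4. The balance of directions was not stable: it was 164 higher and 121 lower without exhausted array 3, and 58 higher and 18 lower with the beta-actin covariate, where 25 of the 106 were kept. Of 37 named calls 21, among them Cd244a, Klrg1, Ccr2 and Anxa1, held in all 15 fits without 1 array, and 22, among them Eomes, Plac8 and Satb1, did not pass with the beta-actin covariate. Of the 15 fits, Sema4a was lost in 14, Eomes and Prpsap1 in 13, Eea1 and Adgrg1 in 12, and Klk8, Ifih1 and Litaf in 10.

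Exhausted and naive cells differed in the largest number of genes among the 6 comparisons. The chemokine gene Ccl5 was 26.1-fold higher in exhausted cells (log2 change 4.71 ± 0.32 SE, adjusted p = 1.36e-05), Fasl 16.8-fold higher (4.07 ± 0.24), granzyme B 14.9-fold higher (3.90 ± 0.28) and interferon gamma (Ifng) 9.86-fold higher (3.30 ± 0.29). The calcium-binding protein gene S100a6 was 11.1-fold higher, Cd244a 10.4-fold, Eomes 9.48-fold and Ccl3 8.60-fold. Tdrp was 13.7-fold lower (1 of 2 probe sets), Dgka 8.91-fold, the sialyltransferase gene St6gal1 8.63-fold (1 of 2 probe sets), the membrane adaptor gene Pag1 7.33-fold (1 of 2 probe sets), Satb1 5.88-fold, Ccr7 5.80-fold and Erdr1 5.44-fold (1 of 2 probe sets). Ighm, the immunoglobulin mu chain of B cells, was 6.97-fold lower, with 2 of its 16 probe sets called and cross-hybridisation possible within the family.

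Effector functions and inhibitory receptors rose together in exhausted over naive cells. Of 15 cytotoxic genes 4 rose, Fasl, Gzmb, Gzma (8.02-fold) and Gzmk (at least 7.04-fold), and 1 fell, with 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00105, or 0.0356 with an estimated correlation). Of 20 cytokines and chemokines 6 rose, including Ccl4 (3.57-fold), and 9 were higher when adjusted over the list alone (adjusted p = 3.30e-05, or 0.048 with an estimated correlation and 0.0755 when exhausted array 3 was also left out). Of 16 inhibitory receptors 7 rose and none fell, among them Ctla4 (6.66-fold), Pdcd1 (5.33-fold) and the prostaglandin receptor gene Ptger4 (4.41-fold), and 10 were higher when adjusted over the list alone, again not independent evidence (adjusted p = 6.07e-09, or 0.031 with an estimated correlation). Of 30 transcription factors 7 rose, among them Bhlhe40 (6.06-fold), Id2 (4.74-fold) and Nr4a2 (3.85-fold), and 2 fell, with 12 higher and 2 lower when adjusted over the list alone (adjusted p = 2.94e-04, or 0.048 with an estimated correlation). Apoptosis and TNF receptor genes included 4 of 20 that rose, such as Tnfrsf1b (3.42-fold), with 7 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0138, or 0.173 with an estimated correlation). Cell cycle genes shifted upward, with 3 of 49 past the test singly, Cdk1 (2.42-fold), the proliferation marker Mki67 (2.23-fold, 1 of 2 probe sets) and Ccnb2 (2.22-fold), and 10 higher when adjusted over the list alone (adjusted p = 6.51e-10, or 0.262 with an estimated correlation).

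Maintenance genes shifted downward in exhausted against naive cells, with 5 of 13 lower and 1 higher by both adjustments (adjusted p = 0.00774, or 0.0669 with an estimated correlation), and included Il7r (3.12-fold lower) and Klf2 (2.34-fold lower). Of 24 T cell receptor signalling genes 3 fell, Dgka, Ptpn6 (2.84-fold) and the kinase gene Tec (2.47-fold), and 2 were higher and 5 lower when adjusted over the list alone (adjusted p = 4.92e-04, or 0.183 with an estimated correlation). Translation factors (none of 40 singly, 7 lower adjusted over the list alone; adjusted p = 0.00102, or 0.186 with an estimated correlation) shifted downward. So did ribosomal proteins, of which Rpl8 fell (2.96-fold; 1 of 35 lower adjusted over the list alone; adjusted p = 0.0447, or 0.479 with an estimated correlation). In the citric acid cycle Idh2 fell (2.64-fold; 2 of 21 lower adjusted over the list alone; adjusted p = 7.53e-04, or 0.395 with an estimated correlation). With the beta-actin covariate, T cell receptor signalling (adjusted p = 0.427), translation factors (0.404), ribosomal proteins (0.412), the citric acid cycle (0.789) and CD4 T cell markers (0.259) no longer passed. Without exhausted array 3 the adjusted p was 0.0512 for T cell receptor signalling, 0.0918 for ribosomal proteins and 0.0736 for CD4 T cell markers, and without effector array 2 it was 0.071 for ribosomal proteins. CD4 T cell markers shifted upward (Tnfrsf4 of 6, 1.64-fold; 2 higher adjusted over the list alone; adjusted p = 0.0277, or 0.282 with an estimated correlation). Lists of trafficking (adjusted p = 0.278), NK-type receptors (0.19), interferon-stimulated genes (0.19), oxidative phosphorylation (0.471), glycolysis (0.476), immediate early genes (0.0621) and B cell markers (0.0707) did not pass. With the beta-actin covariate interferon-stimulated genes (5.67e-15), oxidative phosphorylation (0.00878), trafficking (0.0329) and NK-type receptors (0.044) passed upward and B cell markers (0.00922) downward. The first 2 also passed upward without exhausted array 3 (7.40e-06 and 0.00189), though not with an estimated correlation (0.192 and 0.256). Single members of these changed: the integrin gene Itgb1 (4.14-fold higher), Cxcr3 (3.16-fold higher), Itgb7 (3.64-fold lower, 1 of 2 probe sets) and Pdk1, a kinase that inhibits pyruvate dehydrogenase (4.63-fold lower).

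The test called 470 probe sets between exhausted and naive cells, 190 higher and 280 lower, for 157 and 244 genes. The count was 304, with 181 higher and 123 lower and 203 of the 470 kept, when the beta-actin difference was a covariate. It was 684 without exhausted array 3, with 346 higher and 338 lower. Some folds also rose without that array, to 21.6 for S100a6, 13.8 for Gzma, 13.1 for Ccl3, at least 10.8 for Gzmk and 8.17 for Pdcd1. It was 1388 without exhausted array 2, and 248, 247, 310 and 278 without naive arrays 1, 2, 3 and 4, and 258 and 290 without exhausted arrays 1 and 4. Of 65 named calls 52 held in all 15 fits without 1 array, and 12, among them Prdm1, Cdk1, Mki67 and Ccnb2, did not pass with the covariate. Mki67 and Rpl8 were lost in 13 of the 15 fits, Prdm1 and Cd160 in 12, Bcl2l11 in 11 and Ccnb2 in 10.

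Effector cells at day 8 had higher cytotoxic and migratory transcripts and lower naive ones than naive cells. S100a6 was 34.7-fold higher than in naive cells (log2 change 5.12 ± 0.81 SE, adjusted p = 0.00809), Ccl5 33.0-fold, Klrg1 31.6-fold, granzyme B 25.5-fold (4.67 ± 0.30) and granzyme A 17.8-fold. Ccr2 (16.1-fold), the galectin gene Lgals1 (15.3-fold) and Anxa1 (log2 change 3.59, 2 of 3 probe sets) were also higher. Decreases included Tdrp (16.4-fold, 1 of 2 probe sets), St6gal1 (9.80-fold, 1 of 2 probe sets), Rflnb (8.70-fold), Ccr7 (7.85-fold), the actin crosslinker Actn1 (6.80-fold, 2 of 3 probe sets), the cytokine receptor chain Il6st (6.57-fold, 1 of 2 probe sets), Pdk1 (5.72-fold) and Smad1 (5.58-fold). Il7r fell 5.07-fold.

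Of 15 cytotoxic genes 5 rose, among them Gzmk (at least 7.72-fold) and Fasl (5.64-fold), and 6 were higher and 1 lower when adjusted over the list alone (adjusted p = 3.47e-07, or 0.00437 with an estimated correlation). Of 20 trafficking genes 5 rose, such as Cxcr3 (4.57-fold) and the integrin gene Itga4 (3.95-fold, 1 of 3 probe sets), and 2 fell, with 9 higher and 3 lower when adjusted over the list alone (adjusted p = 6.45e-04, or 0.031 with an estimated correlation). Of 13 maintenance genes 3 fell, Ccr7, Il7r and Lef1 (1.81-fold, 1 of 2 probe sets), and 6 were lower when adjusted over the list alone (adjusted p = 1.26e-05, or 0.00959 with an estimated correlation). Cell cycle genes shifted upward, with 48 of 49 positive, 3 past the test singly, among them Cdk1 (2.20-fold) and Racgap1 (2.01-fold), and 14 higher when adjusted over the list alone (adjusted p = 3.21e-17, or 0.142 with an estimated correlation). Inhibitory receptors shifted upward through Klrg1 and Klrc1 (4.38-fold), 2 of 16, with 4 higher when adjusted over the list alone (adjusted p = 1.51e-05, or 0.0753 with an estimated correlation), while Pdcd1 had a log2 change of 0.32 ± 0.52 (adjusted p = 1). NK-type receptors shifted upward (Klrk1 of 6, 3.92-fold; 1 higher adjusted over the list alone; adjusted p = 4.92e-04, or 0.104 with an estimated correlation). So did cytokines and chemokines (3 of 20 by both adjustments, among them Ifng, 5.53-fold, and Ccl9, 2.01-fold; adjusted p = 0.00651, or 0.158 with an estimated correlation). Oxidative phosphorylation shifted in the same direction with none of 68 past the test (adjusted p = 0.00224, or 0.372 with an estimated correlation). Downward shifts were found for immediate early genes (Fos of 18, 4.80-fold lower, 1 of 2 probe sets; 1 lower adjusted over the list alone; adjusted p = 7.39e-04, or 0.142 with an estimated correlation). Translation factors also fell as a list (Eif4a2, 2.27-fold, and Eif5, 2.11-fold, of 40; 3 lower adjusted over the list alone; adjusted p = 0.0447, or 0.427 with an estimated correlation). B cell markers did as well (Ighm of 19, 3.30-fold lower by 1 of 16 probe sets; 1 lower adjusted over the list alone; adjusted p = 7.39e-04, or 0.403 with an estimated correlation). The transcription factors Bhlhe40 (9.76-fold) and Id2 (5.03-fold) rose, although their list did not pass (adjusted p = 0.178). Without effector array 2 the adjusted p was 0.0503 for cytokines and 0.351 for translation factors. The test called 190 probe sets, 86 higher and 104 lower, for 75 and 89 genes, and the count was 322 without exhausted array 3, 98 and 122 without naive arrays 1 and 4, and 85 without effector array 1. Without effector array 2 it was again 190, but with 119 higher and 71 lower and 126 shared. Of 37 named calls 21 held in all 15 fits without 1 array, while Idh2 was lost in 14, Ccl9 and Fos in 12, Cdk1 in 11, Eif4a2 in 10, Eif5 and Lef1 in 9 and Il6st in 8. The fall of Fos was 3.03-fold without effector array 1 and 7.36-fold without effector array 3, and that of Actn1 4.03-fold without effector array 2. With the beta-actin covariate ribosomal proteins (adjusted p = 0.0175) and the citric acid cycle (0.00843) passed downward, and oxidative phosphorylation (0.0586) did not pass.

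Memory cells had higher levels of cytokine, chemokine and cytotoxic genes than naive cells. Ccl5 was 23.2-fold higher (log2 change 4.54 ± 0.32 SE, adjusted p = 1.81e-05), S100a6 19.4-fold, Ifng 16.4-fold (4.04 ± 0.29), Ctla2b, a cysteine protease inhibitor, 10.1-fold, Klrg1 7.12-fold, Bhlhe40 6.41-fold, Fosb 6.39-fold and Anxa1 6.07-fold (2 of 3 probe sets). Ighm was 8.00-fold lower (2 of 16 probe sets), St6gal1 7.75-fold and Tdrp 5.23-fold (each 1 of 2 probe sets), the integrin gene Itgae 4.87-fold (1 of 2 probe sets), Ramp1 3.00-fold and Tec 2.86-fold. Cnn3 was at least 4.51-fold and Gsn, an actin severing protein, at least 3.19-fold lower, each at the floor on memory arrays. Il7r had a log2 change of 0.78 ± 0.29 (adjusted p = 0.852) and Ccr7 of -1.18 ± 0.24 (adjusted p = 0.0745), neither past the test.

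Of 15 cytotoxic genes Fasl (5.51-fold) and Gzmb (5.04-fold) rose in memory over naive cells, with 4 higher when adjusted over the list alone (adjusted p = 2.62e-11, or 0.00179 with an estimated correlation). Of 20 trafficking genes 4 rose, among them Cxcr3 (5.83-fold), Ccr2 (5.69-fold) and Itgb1 (3.69-fold), and 4 were higher and 3 lower when adjusted over the list alone (adjusted p = 0.00103, or 0.0356 with an estimated correlation). Immediate early genes shifted upward, with Fosb the only one of 18 past the test by either adjustment (adjusted p = 1.27e-07, or 0.0398 with an estimated correlation and 0.0656 when exhausted array 3 was also left out). Inhibitory receptors did so through Klrg1 alone of 16, with 4 higher when adjusted over the list alone (adjusted p = 9.98e-07, or 0.048 with an estimated correlation). Cytokines shifted upward (Ccl5 and Ifng of 20 by both adjustments; adjusted p = 6.63e-05, or 0.052 with an estimated correlation). Transcription factors did too (3 of 30, among them Id2, 4.26-fold, and Klf4, 3.50-fold by 1 of 2 probe sets; 5 higher and 2 lower adjusted over the list alone; adjusted p = 0.0043, or 0.118 with an estimated correlation), and so did NK-type receptors (Klrk1 of 6, 3.81-fold; 1 adjusted over the list alone; adjusted p = 0.00163, or 0.142 with an estimated correlation). The shifts of apoptosis genes (Fasl of 20; 1 adjusted over the list alone; adjusted p = 0.00628, or 0.142 with an estimated correlation) and glycolysis genes (none of 15; 1 lower adjusted over the list alone; adjusted p = 0.00849, or 0.142 with an estimated correlation) were also upward. B cell markers shifted downward, with Ighm the only one of 19 past the test and 4 lower when adjusted over the list alone (adjusted p = 2.62e-11, or 0.118 with an estimated correlation). B cells in some naive samples were not excluded as a source of this shift, or of that in effector cells. The test called 63 probe sets, 42 higher and 21 lower, for 35 and 19 genes, and 96 without exhausted array 3. Of 27 named calls 22 held in all 15 fits without 1 array, and Ctla2b was lost in 13 and S100a6 and Idh2 in 8.

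Memory and naive arrays of the same number deviated together from their group means in all 4 pairs (r = 0.414 to 0.707). With the number as a block in a fit of these 8 arrays, an alternative chosen after seeing the data, the count was 195, with 115 higher and 80 lower and 46 of the 63 kept. In that block fit Bhlhe40 (adjusted p = 0.0801), Itgae (0.0676) and Klf4 (0.0566) did not pass, nor did Il7r (0.0676) and Ccr7 (0.062). Eomes (0.033) and Cd7 (0.0434), which had not passed in the main fit, passed upward. NK-type receptors no longer passed as a list (0.0577), and cell cycle genes (0.00973) and oxidative phosphorylation (0.00836) passed upward.

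Few genes passed the test between memory and effector cells, led by immediate early and maintenance genes. The immediate early list can also reflect sample handling. The low count does not show that the cells are alike, because the spread of all 4 groups enters the test. Gzma was not called at 11.21 ± 0.34 (SD) in effector and 7.70 ± 0.54 in memory cells, with an SD of 1.63 in exhausted cells. Fos was 12.2-fold higher in memory cells (log2 change 3.61 ± 0.49 SE, adjusted p = 0.0122, 1 of 2 probe sets), Il7r 8.68-fold (3.12 ± 0.31, adjusted p = 0.00206), Fosb 7.47-fold, Bcl2 5.24-fold (2 of 3 probe sets), Rflnb 4.61-fold, Klf4 4.51-fold (1 of 2 probe sets), Ccr7 3.47-fold and Tdrp 3.14-fold (1 of 2 probe sets). The 4 lower genes were granzyme B (5.06-fold), Itgax (2.44-fold), the ATP synthase inhibitor Atpif1 (1.48-fold) and Pdlim7 (1.12-fold, 1 of 4 probe sets, near the floor). Immediate early genes rose as a list (2 of 18 singly, 6 adjusted over the list alone; adjusted p = 2.25e-17, or 0.00437 with an estimated correlation). Maintenance genes rose as well (2 of 13 singly, 6 adjusted over the list alone; adjusted p = 1.08e-09, or 0.00179 with an estimated correlation). Cell cycle genes shifted downward, with none of 49 past the test singly and 2 lower when adjusted over the list alone (adjusted p = 1.67e-19, or 0.12 with an estimated correlation). Oxidative phosphorylation (none of 68 by either adjustment; adjusted p = 0.00833, or 0.427 with an estimated correlation) and macrophage, monocyte and dendritic cell markers (Itgax of 21; 1 higher and 3 lower adjusted over the list alone; adjusted p = 0.0114, or 0.397 with an estimated correlation) also shifted downward, but neither passed without effector array 2 (adjusted p = 0.0589 and 0.355). The test called 24 probe sets, 20 higher and 4 lower, for 17 and 4 genes. The count was 54 without effector array 2, with 26 higher and 28 lower, and 59 without exhausted array 3, 41 without exhausted array 2, 9 without effector array 1 and 15 without memory array 2. The rise of Fos was 7.67-fold without effector array 1 and 18.6-fold without effector array 3. Of 12 named calls those of Fos, Il7r, Rflnb and Klf4 held in all 15 fits without 1 array. With the beta-actin covariate ribosomal proteins (adjusted p = 0.00954), translation factors (0.00562) and the citric acid cycle (0.0428) passed upward, and oxidative phosphorylation (0.0823) no longer passed.

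Many changes from the naive state were shared by the 3 antigen-experienced groups. Effector and memory cells shared 34 higher and 20 lower probe sets, effector and exhausted cells 31 and 73, and memory and exhausted cells 19 and 21, and no probe set was called in opposite directions in any pair. In all 3 groups 17 probe sets were higher and 20 lower. Independent draws would have shared 0.176 to 2.34 per direction, but the comparisons share their naive arrays. Simulated unchanged groups with shared simulated naive arrays had at most 1 call in common. Each probe set was simulated with independent noise, without the deviations that real arrays show together. The simulation therefore does not bound the sharing that common naive arrays can cause. With naive arrays 1 and 2 used for one comparison and 3 and 4 for the other, and the reverse, effector and memory cells still shared 18 higher each way and 14 and 13 lower, and effector and exhausted cells 9 higher each way and 28 and 27 lower.

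Exhausted cells were set apart from all 3 other groups by 43 probe sets, 20 higher (16 genes) and 23 lower (20 genes). Among those higher, Cd244a exceeded the other groups by log2 changes of 3.35 ± 0.27 (memory), 3.24 ± 0.30 (effector) and 3.38 ± 0.27 (naive), and Rgs16 by at least 2.53. Tnfrsf9, a costimulatory receptor at the floor in all other groups, was at least 3.50-fold higher. The smallest of the 3 log2 changes was 1.72 for Eea1, 1.71 for Ifih1, a sensor of viral RNA, 1.69 for the adhesion receptor gene Adgrg1, 1.58 for Fasl, 1.53 for Nr4a2, 1.41 for Lclat1, 1.29 for Itgav, 1.22 for Ccrl2 and 1.04 for Litaf. Among those lower it was -1.81 for Itgb7, -1.65 for the actin-binding gene Twf2, -1.57 for Satb1, -1.40 for Ptpn6, -1.34 for Klrd1, -1.26 for Klk8, -1.24 for Sema4a, whose exhausted and naive arrays overlapped, and -1.18 for Gm2a, a lysosomal activator of ganglioside breakdown. It was -0.98 for Slco3a1, -0.86 for Icam2, -0.71 for Ugcg, the first enzyme of glycosphingolipid synthesis, and -0.70 for Prpsap1. Without exhausted array 3 the count was 133, 98 higher and 35 lower, and 41 of the 43 were kept. Pdcd1 (smallest log2 change 2.71) and Cd160 (1.49) were among those added.

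With the beta-actin covariate, 42 probe sets were higher and 5 lower, and only 11 of the 43 were kept. A lost call need not mean a smaller change. For the 138 called lower than memory, the covariate took the median change from -0.942 to -0.804 and the median standard error from 0.155 to 0.189. The count was 318 without exhausted array 2. It was 20 to 28 without naive array 1 or 2, effector 1, memory 1, 2 or 4, or exhausted 1 or 4.

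**Figure D4:**
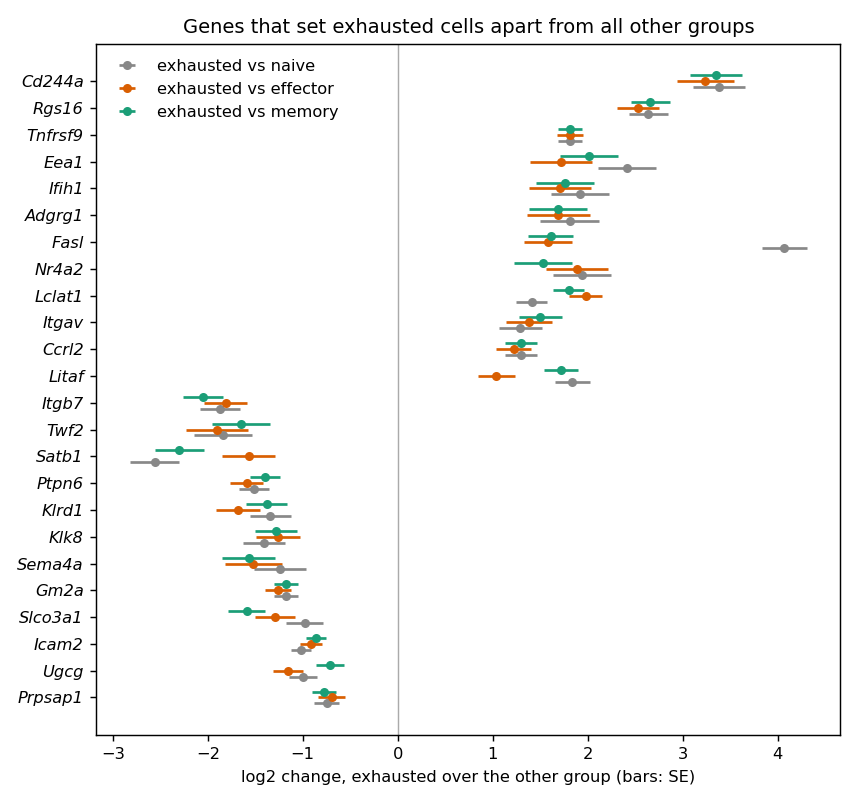
Log2 change of exhausted cells over each other group for the 12 genes most above and the 12 most below all 3 groups. Points are limma estimates from the 15 A arrays and bars are SE, with colours for the group compared; Cd244a has the largest smallest change, 3.24, and Itgb7 the largest decrease by the same measure, -1.81.

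The B and C arrays covered further genes, with 2 exhausted arrays and 1 array of each other group. On the B arrays, 51 probe sets were at least 2-fold higher and 74 at least 2-fold lower on both exhausted arrays than on each other array. Maf, a transcription factor of interleukin 10 expression, was at least 9.19-fold higher on both arrays, and the signalling inhibitor Spry2 7.04-fold, Setbp1 5.98-fold, Chn2 4.59-fold and Rpgrip1 4.39-fold. Satb1 was 4.30-fold lower, in the direction of its A array probe set, followed by the lamin B receptor gene Lbr (4.05-fold), Arhgef18 (3.97-fold), Gramd3 (3.69-fold) and Lrrc47 (3.50-fold). On the C arrays 48 probe sets were higher and 30 lower by this measure. Prr5l was 15.2-fold higher, Izumo1r, a folate receptor family member of regulatory T cells and also among the CD4 T cell markers, 10.2-fold, Maf 6.23-fold, Dnase1l3 5.59-fold and Cemip2 4.67-fold. Klhl6 was 5.19-fold lower, Farsb, at the floor on both exhausted arrays, at least 4.69-fold, the scaffold gene Iqgap1 4.11-fold, Zbtb44 3.60-fold and Herc4 3.21-fold.

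Each fold on the B and C arrays is the smallest between an exhausted and another array. No probe set on these arrays passed limma between exhausted and memory cells, although 1838 on B and 1867 on C had an unadjusted p under 0.05, and the smallest adjusted p was 0.179 and 0.168. Fitted with a variance trend, limma called 111 and 129. By order alone, with no minimum fold, both exhausted arrays lay above all others for 2131 and 2133 probe sets and below them for 2645 and 2973, where random order gives 10% each way.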

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

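The exact tests of RNA quality, the slope tests of exhausted array 2, the equal sets, the sizes with the covariate, the split of array 3 by direction and its comparisons with probe sets of the same level, the comparison of exhausted array 3 with the beta-actin range and the test of B cells in the naive sort were chosen after the result was seen, the slope tests once the counts without each array and with the beta-actin covariate were known and the 2-fold margin for array 3 once the shares without a margin were known.

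Other splits of the same arrays were tested for each count of changed probe sets. For exhausted against memory cells 1 of 35 splits, the real one with 218, gave as many (highest other 158). So it was for exhausted against naive (1 of 35, 470 against 2), effector against naive (1 of 35, 190 against 5) and memory against effector (1 of 35, 24 against 3). For these 4 counts the real split thus gave the most. A share of 1 in 35 is the smallest these splits can give. It was not adjusted over the comparisons, so the share alone does not exclude chance. Effector array 3 also deviated from its group mean together with naive array 4 (r = 0.781) and memory array 4 (0.732). Other effector pairs were as low as -0.689 (effector array 2 with naive array 4). The effector splits made no allowance for such pairs. Naive and memory arrays pair by number, and the 8 splits that part all 4 pairs are too few for a share under 1 in 20 (63 in the real split, highest other 0); the other 27, which keep some pairs together, gave at most 1. Among 100 random regroupings of the 15 arrays, only the real one gave as many as the 43 probe sets that set exhausted cells apart (highest other 0). These regroupings mix all 4 groups, so they exclude only that the groups are all alike. The 43 must also pass against effector cells, the comparison taken up next. For exhausted against effector cells 5 of 35 splits gave at least the real 106, so chance was not excluded. The highest, 1200, came from effector array 2 with exhausted arrays 1, 3 and 4 against effector arrays 1 and 3 with exhausted array 2, and others gave 817, 706 and 165, which points to a structure of the samples across both groups.

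The calls for exhausted cells changed when the beta-actin 3' to 5' difference was a covariate, which rested largely on exhausted arrays 2 and 3. The difference was high on arrays 1, 3 and 4 and within the range of other groups on array 2. Among the 392 probe sets called lower than memory without array 2, array 2 showed a fraction of 0.398 of the fall of the other 3 arrays (95% interval 0.336 to 0.461), below the bound of 0.5 set for RNA quality, and among the 319 called higher 0.589 (0.47 to 0.696), between the bounds of 0.5 and 0.8, low values that the rise in counts without array 2 had foreshadowed. In sets of 200 probe sets per array, chosen by the change of the other 3 arrays alone, the fraction for arrays 2, 4, 1 and 3, in the order of their beta-actin differences, was 0.336, 0.732, 0.961 and 1.11 of the fall but 0.657, 0.998, 1.13 and 0.051 of the rise, so the array with the highest difference hardly rose. With the covariate the median fall of the 138 probe sets called lower went from -0.94 (quartiles -1.33 and -0.66) to -0.80 (-1.24 and -0.54) and the median rise of the 80 called higher from 0.99 (0.64 and 1.58) to 1.10 (0.61 and 1.86), and calls ended for all but 45 and 41 as the median standard error grew from 0.155 to 0.189 and from 0.182 to 0.224. RNA quality and a milder state on array 2 cannot be told apart for either direction, because arrays 2 and 3 point opposite ways for the rises, most of the fall stayed with the covariate, and no label records viral load or RNA integrity.

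Exhausted array 3 stood apart, with 0.464 (0.38 to 0.555) of the change from memory that the other exhausted arrays showed over 367 probe sets. This was made of 0.174 for increases (0.0831 to 0.271) and 0.966 for decreases. A wrong label was predicted to give under 0.2, but the value also fell short of the bound set for a right label, so this test did not decide. The fraction that a naive or effector array would show over these probe sets was not measured. Of 133 probe sets that set the other exhausted arrays apart, 48.9% (40.1 to 57.7) lay beyond all 11 other arrays on array 3. A naive, effector or memory sample was predicted to give at most 25%, but the share fell short of the bound set for a right label, so it did not decide either. Of those higher it was 41.8% (31.9 to 52.2) against 34.7% of probe sets of the same level, and of those lower 68.6% (50.7 to 83.1) against 30.9%. Beyond by at least 2-fold lay 7.14% of those higher (2.92 to 14.2, against 1.94%) and 25.7% of those lower (12.49 to 43.3, against 9.07%). Cd244a (8.07, highest of the 11 other arrays 6.05) and Ctla4 (8.44, highest other 7.12) stood further above than all 200 probe sets of the same level, though Pdcd1, Lag3 and Cd160 did not. These later comparisons speak against a sample wholly of another group, but the planned tests were undecided and a mixed sample stays open. Poor RNA may account for part of it, since its beta-actin difference of 2.8 was above all other arrays (highest other 1.93), although its Gapdh difference of 2.64 was not. Cells of another type cannot be told apart. The highest marker list, platelets with 4 genes, lay 0.447 above genes of the same level (0.161 to 1.31). Neutrophil markers lay 0.413 above (0.137 to 0.609), although the cells had been flow sorted.

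Ighm was higher in naive than in memory cells by a mean log2 difference of 2.48 over the 2 of 16 probe sets called. If B cells in the naive sort were the source, the other 18 B cell markers were predicted to rise by at least 1.24, and if not, by under 0.62; their median rise was 0.246 (0.194 to 0.916). The interval reaches past the lower bound and weak or high-baseline markers would hide a small share. B cells therefore cannot be told apart from a change in the T cells, although the cells had been sorted. On naive array 4 Ighm was 10.33 (memory mean 7.135) while Cd74 (7.56) and Blk (6.151) lay below their memory means of 8.106 and 6.316, but it is 1 array. On naive arrays 1 to 3 Cd74 (10.53, 10.18 and 9.508) and Blk (7.901, 7.853 and 7.722) lay above these means, as B cells would give. H2-Aa did so too (10.39, 10.28 and 9.768, memory mean 7.667), whereas Pax5 hardly differed (naive mean 7.503, memory mean 7.409). The biological explanation, Ighm transcripts of naive T cells, was not tested.

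Of 354 groups of 4 arrays tested for the named genes, 36 had 1 array far from the other 3, where chance flags about 1 in 20 groups (17.7 expected); 10 of these were exhausted array 3, 7 naive array 4 and 6 naive array 3. All values are log2 intensities.

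On exhausted array 3, Plscr1 (10.90; others at most 8.73), Fosb (10.66), St6gal1 (6.57), Cnn3 (5.38) and Idh2 (7.70) were above the other 3 arrays. Ccl5 (12.31), S100a6 (6.79; others at least 10.25), Ctla2b (5.55; others at least 8.38), Atpif1 (8.96) and Entpd1 (6.13) were below them. On exhausted array 2, Rgs16 (8.51) and Eomes (7.50) were below and Eif4a2 (10.60) and Sema4a (9.57) above, and on exhausted array 1 Klk8 (5.88) was below.

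On naive array 4, Eomes (5.75), Tdrp (10.97), Itgae (8.25), Pdlim7 (5.19), Rsad2 (7.78) and Ptger4 (8.13) were above the other 3 arrays and Twf2 (8.92) below. On naive array 3, Ighm (9.46), Pdk1 (8.74), Rpl8 (12.41) and Sema4a (9.46) were below and Klrd1 (10.47) and Dnajb1 (7.99) above. Among memory arrays, Cd244a (5.55), Gzmk (5.88, array 3) and Ccl9 (5.49) were low on 1 array, the first and last on array 4. Rgs16 (6.80, array 2), Tdrp (8.66, array 4) and Cdk1 (7.89, array 3) were high on 1 array. Itgae (5.21) on memory array 2 and Pdlim7 (5.16) on memory array 1 were singled out only because the other 3 arrays lay at the floor, as were Pdlim7 on naive array 4 and Cnn3 on exhausted array 3, and are not read as differences in level.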

How the results depend on the processing

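The beta-actin and first-component covariates, the removal of exhausted array 3 with effector array 2, the removal of probe sets at the floor and the alternatives for the overlap were chosen after the result was seen, as was the replicate block of only the naive and memory arrays. The cause of the differences was not tested except where stated. Counts of changed probe sets are in the order exhausted against memory (218), effector (106) and naive (470), effector against naive (190), memory against naive (63) and memory against effector (24), then exhausted-distinct (43), then called in all 3 groups against naive (37).

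With only the 2 groups compared in the fit, and so fewer arrays behind the spread, they were 60, 5, 122, 113, 109, 3, 2 and 17. Array weights gave 2636, 2763, 2834, 1719, 480, 1083, 1328 and 227, and the first-component covariate 1534, 892, 2535, 484, 135, 105, 522 and 85. Both use the residuals that the test also uses, so their p-values are too small. Without exhausted array 3 and effector array 2 they were 584, 238, 963, 398, 126, 119, 113 and 69. At a minimum of 2-fold, the first 4 were 101, 59, 203 and 117 and the exhausted-distinct count 25, by construction. The beta-actin covariate gave 304 for exhausted against naive and 40 for memory against effector. With the numbers as a replicate block in a fit of only the naive and memory arrays, memory against naive gave 195. A replicate block over all 15 arrays, of which 8 correlated best with their own number, gave 217, 80, 466, 138, 60 and 12. Memory against effector was also 45 above the median level, and 38 without probe sets at the floor, where the exhausted-distinct count was 71.

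Leaving out 1 array gave ranges of 93 to 711, 45 to 539, 247 to 1388, 85 to 322, 49 to 96, 9 to 59, 20 to 318 and 29 to 57, and 55 to 64 lists (60 with all arrays). At least 1 count of changed probe sets moved by over 1.5-fold without each array except effector array 3 and memory array 3. The highest counts came without exhausted array 2 or 3, so removal of array 3 is not a correction. Of 60 list calls 15 passed with an estimated correlation and 38 of the same with fry, and 46 were kept without exhausted array 3. With the beta-actin covariate 41 of 60 list calls were kept and these turned: T cell receptor signalling (adjusted p = 0.844 against memory, 0.683 against effector) and the citric acid cycle (0.85 and 0.186) in exhausted cells, none passing, and interferon-stimulated genes in effector against naive cells, which then fell (0.0442) without having passed before.

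Of 234 calls of named genes none changed sign in any fit, and 211 were kept with values as deposited, 209 with median centring, 232 and 208 with floors at the 10th and 40th percentiles, 230 with a variance trend, 103 with only 2 groups, 192 with a replicate block and 176 with the beta-actin covariate. On the B and C arrays a gap of 1.5-fold gave 417 and 376 in place of 125 and 78, and leaving out 1 exhausted array gave 198 to 208 and 132 to 172, by construction. A variance trend called 111 and 129 there where none was called without it. Signals near the floor limit the folds, which are lower bounds where a group lay at it.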

Other observations

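The following values were read without a planned test.

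On the B and C arrays single genes of the fixed lists differed between groups with no spread to test them. Tox, a transcription factor of CD8 T cell differentiation, had log2 intensities of 7.41 and 7.72 on the exhausted B arrays, against 6.65 in naive, 5.20 in effector and 5.04 in memory cells. On the C arrays another Tox probe set exceeded memory by a log2 difference of only 0.0189. Dapl1, a naive cell gene, was 8.46 in naive, 4.28 in effector, 4.43 in memory and 6.40 and 6.03 in exhausted cells on the B arrays. Its C array probe set differed, with 9.97 in naive, 9.60 in effector and 9.45 in memory cells and the lowest values, 9.196 and 9.252, in exhausted cells. Serpinb6b, a granzyme inhibitor family gene, was 7.41 in effector, 7.19 and 6.86 in exhausted, 5.39 in memory and 4.995 in naive cells. The integrin gene Itga1 was 7.80 in effector, 6.87 in memory, 5.71 in naive and 5.32 and 5.67 in exhausted cells on the C arrays, and the cytotoxic granule gene Nkg7 was 12.63, 12.07, 11.14, and 12.47 and 12.86 in the same order.

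Across the 15 A arrays, the first principal component held 37.9% of the variance and placed exhausted array 3 at 71.6, with the next highest, effector array 2, at 27.7. The first component of deviations from group means held 53.6% of those deviations, with the highest scores on the same arrays (0.682 and 0.382).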
